A study of Mus musculus with 4 samples.

How the data were processed

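Testis RNA of 4 samples was analysed, 2 from WT and 2 from Tas1r3-deficient male mice, grouped by the titles in the labels. Per the labels' protocols, libraries were made from total RNA with an Ion Torrent total RNA kit, so ribosomal RNA could enter the libraries. Per the submitters' processing notes, STAR and Partek were used on the mm39 genome; versions, settings and annotation release are not given in the sources used here. The deposited values are CPM per RefSeq transcript, scaled by the authors so that each column summed to 1000000. The table of the series and the 4 sample tables held identical values in 4 of 4 columns. No deposited column of values was left unused.

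The tables listed 29342 transcripts of 17924 gene symbols, with 0 mitochondrial transcripts, so the list of mitochondrially encoded transcripts could not be tested. Transcript values were summed per gene symbol. In each library the commonest low values were multiples of a step taken as the value of 1 read, 0.582, 0.553, 1.34 and 1.67 CPM in WT samples 1 and 2 and KO samples 1 and 2. This gave estimated depths of 1719356, 1807694, 748637 and 597936 assigned reads. Among genes with a level of at least 0.5 reads, 23.0%, 26.5%, 48.1% and 47.4% came out whole within 0.02 reads, so reads had been divided between transcripts and whole counts were not recovered. Read numbers in the text are therefore rounded estimates. Intervals and floors (3 reads, 95%) cover counting error only. Identical values with another gene were found for 190 genes, and genes with near copies are uncertain. List members were matched by exact symbol, and those without a matching tested symbol were left out (524 of 592 were tested).

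Genes with at least 1 CPM in at least 2 of 4 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1) with a mean trend, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The share of genes with an unadjusted p under 0.05 within 5 Mb of Tas1r3 was set against other chromosomes with a two-sided Fisher's exact test. A permutation of 2 against 2 samples has 3 splits and cannot give a two-sided p below 0.333, so no permutation test of single genes was used. Positions are those in the deposited tables. The reference annotation of an older build was not used here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled the tables and drew the figures.

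The gene lists, the 5 Mb window, the thresholds and the rule for named genes were fixed before the data were examined. Named genes were Tas1r3, Tas1r1, Tas1r2 and Gnat3; up to 10 genes per direction with the greatest absolute log2 fold change among those with adjusted p under 0.05, genotypes that did not overlap and a mean of at least 5 CPM, with open places filled by smallest p; the 3 members of each list with the smallest p (4 for Leydig cells); and up to 5 genes of the window with adjusted p under 0.05. Unnamed gene models were left out of naming; 2248 were tested and 138 had an unadjusted p under 0.05. A gene that the rule selects is not reported here.

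The procedure was tested on simulated data at these depths in 20 draws of about 17602 genes. It called 30.0% of genes changed 2-fold, 71.1% changed 4-fold and 85.0% changed 8-fold, and 5 of 348036 unchanged genes. The changed genes were drawn only from genes with a mean of at least 5 CPM, so their shares do not cover lower genes, which were also tested. A shift of 0.5 in the Leydig cell list was called in 20 of 20 draws. Every simulated gene had the same spread between samples (SD 0.112 on the log2 scale, the median of genes at 500 CPM or more). Simulated genes also varied independently. Lower genes may vary more in the data, and genes of a list may vary together, so these shares need not hold for the data. Alternatives covered the pseudocount, the filter, rescaling by trimmed mean of M values, quantile normalization, the mean trend, the replicate number as a block, the window size and each sample left out. Precision weights from the estimated reads, a window of 10 Mb, a window without the genes within 1 Mb of Tas1r3 and a blood cell list without haemoglobin genes were added after the data were seen.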

Results

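Bulk RNA sequencing measured transcript levels in testes of male C57BL/6 mice that had eaten a normal diet for 18 weeks. There were 2 wild-type (WT) samples and 2 samples from mice deficient in Tas1r3 (KO). Tas1r3 encodes the shared subunit of the sweet and umami taste receptors, which are also made in testis. The series asks how testicular gene expression differs when this subunit is missing. The step between low values gave an estimated 1719356 and 1807694 assigned reads in WT samples 1 and 2, and 748637 and 597936 in KO samples 1 and 2. Mean depth was therefore 2.62 times higher in WT, and no sample of one genotype had the depth of the other. Levels are given in CPM (read counts scaled to a common total of 1000000) per gene as mean ± SD with n = 2 per genotype, and fold changes are KO over WT on the log2(CPM + 1) scale, which understates changes of low genes. The labels do not say that the samples of a genotype came from separate animals, so p-values measure the spread between these samples.

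The targeted gene was nearly undetected in both KO samples. Tas1r3 stood at 13.8 and 20.5 CPM in the WT samples and at 1.34 and 0 CPM in the KO samples. These values correspond to about 61 reads over the WT group and 1 read over the KO group, a KO level of 4.29% of WT (exact 95% interval 0.107% to 24.8%, counting error only). The count of 0 in KO sample 2 allows up to 5.02 CPM, the value of 3 reads. Tas1r3 lies on chromosome 4 of mm39, from 155943726 to 155947811 on the minus strand, with a transcript of 3513 bases. Its log2 fold change was -3.54 (SE 0.60). In limma with Benjamini-Hochberg adjustment over all tested genes this did not pass (adjusted p = 0.942); it passed without KO sample 1 (-4.16, adjusted p = 1.61e-12) and without KO sample 2 (-2.93, adjusted p = 2.51e-07). The log2 fold change was -5.48 with a pseudocount of 0.1 and -1.96 with a pseudocount of 5. The part of the gene that was deleted is not given in the sources used here.

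Of 17744 genes tested, 1 (Ptchd3) passed the adjusted threshold as lower in KO testis, and 0 passed as higher. Each split of the samples that mixed the genotypes also gave 1 gene past this threshold. Ptchd3, a patched domain protein of sperm, stood at 252 ± 16.6 CPM in WT and 57.7 ± 6.21 CPM in KO, which is 4.32-fold lower on the log2(CPM + 1) scale. It lies on chromosome 11 from 121721044 to 121734263, away from the targeted locus. Its log2 fold change was -2.11 (SE 0.16, limma adjusted p = 0.0197), and both KO samples were below both WT samples. At an unadjusted limma p under 0.05 there were 243 genes higher and 590 lower, together 833 where 887.2 would be reached by chance. Among these, 70.8% were lower in KO. That share was 54.1% after quantile normalization, which gives each library the same distribution of values and so evens out such a shift by construction. It was 42.4% (477 higher, 351 lower) with precision weights for depth, which were added after the data were seen. The weighted fit also used a pseudocount in reads, which adds more CPM in the KO samples than in WT, and no mean trend. Its share is therefore not an effect of the weights alone. The genotypes did not overlap in 6111 genes (34.4%), where chance gives 33.3%.

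The adjusted counts moved with single samples and with the weighted fit. Precision weights gave 4 higher genes (Mxra8, Rn18s, Sord and Tas1r1) and 1 lower gene (Ptchd3). Without KO sample 1 there were 434 higher and 1029 lower genes, and without KO sample 2 there were 146 and 510; the spread then came from the WT samples alone. Without WT sample 1 the counts were 1 and 3, and without WT sample 2 they were 5 and 3. Ptchd3 did not pass without a mean trend (adjusted p = 0.247) or with a pseudocount of 0.1 (adjusted p = 0.152), and its log2 fold change lay between -2.22 and -2.00 when any 1 sample was left out.

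No other gene passed, and the values that follow are of the genes with the smallest p among those whose genotypes did not overlap. On the higher side, Mxra8, an adhesion protein of the cell surface, was at 34.5 ± 2.23 CPM in WT and 84.9 ± 12.2 CPM in KO. Sord, the sorbitol dehydrogenase that makes fructose from sorbitol in sperm, was at 1436 ± 11.4 and 2036 ± 126 CPM. Vamp3, a vesicle fusion protein, was at 44.0 ± 1.70 and 75.0 ± 9.13 CPM. The 18S ribosomal RNA gene Rn18s was at 12906 ± 1354 and 18460 ± 1255 CPM, the highest level of any gene in all 4 libraries, and quantile normalization sets its difference to 0.00. Prss47, a serine protease, was at 11.1 ± 1.6 and 24.7 ± 2.86 CPM, and Tex9 at 29.1 ± 5.37 and 52.3 ± 8.33 CPM. Psme2b was at 5.88 ± 1.44 and 16.9 ± 0.25 CPM, and Mblac2 at 2.28 ± 0.88 and 10.2 ± 2.61 CPM. Psme2b is a near-copy of a proteasome activator gene, so its reads are uncertain.

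On the lower side, Kcnab2, a potassium channel subunit, was at 62.5 ± 0.29 CPM in WT and 32.8 ± 4.99 CPM in KO. Atp6v0c, a subunit of the proton pump of acidic vesicles, was at 42.8 ± 12 and 19 ± 0.38 CPM. Eif4ebp2, a repressor of translation initiation, was at 20.05 ± 2.83 and 5.33 ± 1.91 CPM. Ap3m2, an adaptor protein of vesicle coats, was at 15.3 ± 1.91 and 3.68 ± 0.47 CPM, and Gsdma, a gasdermin, at 16.3 ± 2.35 and 3.01 ± 0.48 CPM. In KO samples 1 and 2, Ap3m2 had about 3 and 2 reads, and Gsdma about 2 in each. The small KO SDs of these 2 genes therefore do not show close agreement between the samples. Tmed5 had about 38 reads in WT and 1 in KO, a ratio of 0.069 (exact 95% interval 0.0017 to 0.408). The kinase genes Smok3b and Smok3c, neighbouring near-identical copies on chromosome 5, differed in opposite directions. Smok3b was at 0.34 ± 0.05 CPM in WT and 18.97 ± 5.04 CPM in KO, about 1 and 25 reads. Smok3c had about 37 reads in WT and was below 0.5 reads in each KO sample, at least 4.69-fold lower against a floor of 3 reads over the KO group. Summed over 3 Smok3 copies the level was 27.0 ± 4.98 CPM in WT and 33.0 ± 20.2 CPM in KO.

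**Figure D1:**
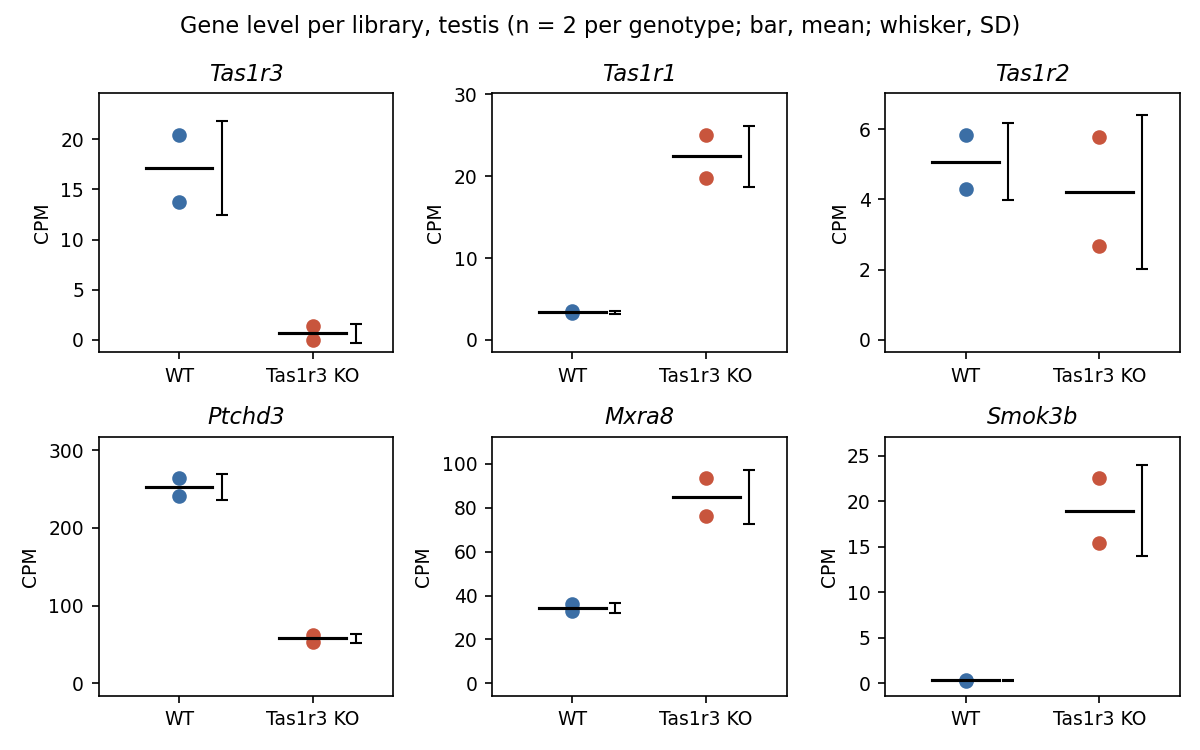
Level in CPM (vertical axis) of 6 genes in each testis library by genotype (horizontal axis); points are libraries, horizontal bars are means and whiskers are SD, n = 2 per genotype. Tas1r3 was at 1.34 and 0 CPM in the KO libraries, while Tas1r1, Mxra8 and Smok3b lay above both WT libraries and Ptchd3 below them, and of these genes Ptchd3 alone passed the adjusted test.

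Among the other taste receptor genes, Tas1r1, the umami partner of TAS1R3, was at 3.38 ± 0.21 CPM in WT and 22.4 ± 3.74 CPM in KO. Its log2 fold change was 2.41 (SE 0.39), with limma adjusted p = 0.942 over all genes. Tas1r2, the sweet partner, was at 5.07 ± 1.10 and 4.22 ± 2.20 CPM, a difference within the spread. Of 8 tested members of the list of taste receptors and taste signalling, 0 passed over all genes, and 1 (Tas1r1) rose when adjusted over the list alone (adjusted p = 0.0024). The calcium channel gene Itpr3 was at 33.3 ± 7.93 and 28.7 ± 1.98 CPM. The transducin gene Gnat1 had about 7 reads in WT and 2 in KO, a depth-scaled ratio of 0.75 (exact 95% interval 0.076 to 3.93). Gnat3 had no values in the tables used here. The list as a whole did not pass (camera adjusted p = 0.899), and its median of -0.16 and mean of 0.14 differed in sign.

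Genes with small p-values were more frequent around Tas1r3 than on other chromosomes. Within 5 Mb of it, a window that ends at the last gene of chromosome 4, 12 of 92 tested genes (13.04%) had an unadjusted p under 0.05. On other chromosomes there were 762 of 16630 (4.58%; odds ratio 3.12, 95% interval 1.54 to 5.79, two-sided Fisher's exact p = 0.0011). In the window 7 of these genes were higher and 5 lower, and 0 passed over all genes. Fisher's test counts neighbouring genes of the same samples as independent, which they need not be. Adjusted over the window alone, Mxra8 and Tas1r1 passed (adjusted p = 0.0135 for each). Mxra8 starts at 155924137 and Tas1r1 at 152112371 on chromosome 4. Vamp3 and Kcnab2 also lie there, as does Ints11, a subunit of the Integrator complex chosen after its values were seen, at 36.4 ± 6.95 CPM in WT and 16.5 ± 4.40 CPM in KO. The share was 8.70% against 6.30% elsewhere without a mean trend (exact p = 0.384) and 31.9% against 23.6% elsewhere without KO sample 1 (exact p = 0.082). It was 28.9% against 18.0% elsewhere without KO sample 2, 5.56% against 1.15% without WT sample 1 and 8.79% against 1.15% without WT sample 2, each with an exact p under 0.05.

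**Figure D2:**
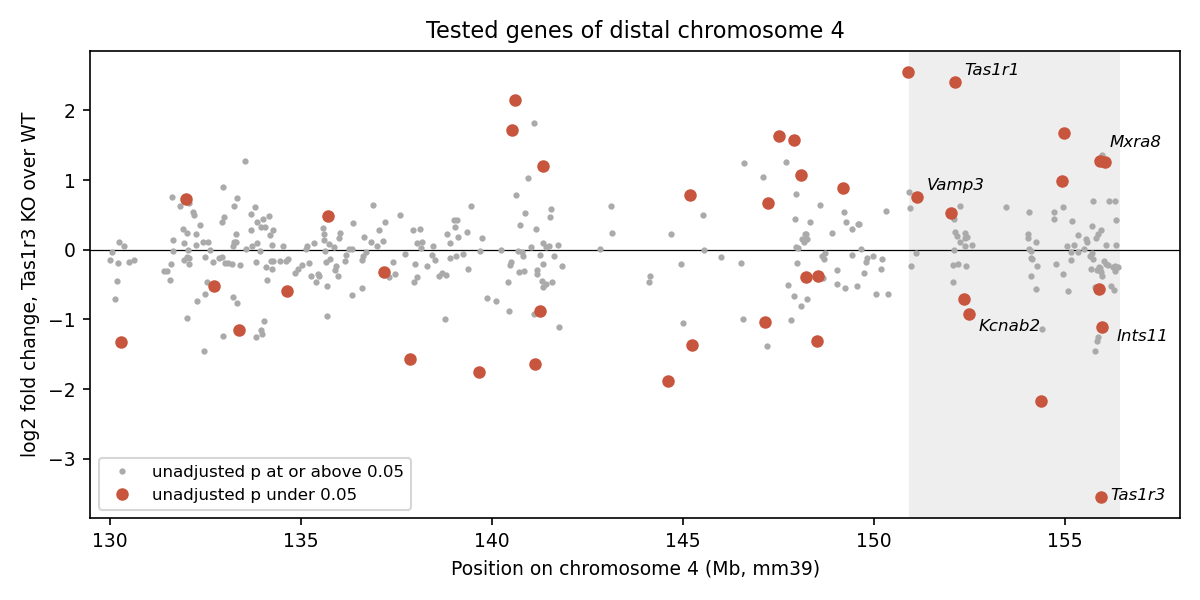
Log2 fold change of KO over WT (vertical axis) of each tested gene against its position on distal chromosome 4 in Mb of mm39 (horizontal axis); red points have an unadjusted limma p under 0.05, grey points do not, and the shaded band is the window of 5 Mb around Tas1r3. In the band 12 of 92 genes other than Tas1r3 are red, 7 above 0 and 5 below.

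Of 28 gene lists tested, covering 524 tested genes, 1 was called. In the list of blood cells all 7 tested members were lower in KO (median log2 fold change -0.94, camera adjusted p = 0.0346), and it was not called with an estimated correlation (adjusted p = 0.981). The haemoglobin gene Hbb-bt had about 24 reads in WT and was below 0.5 reads in each KO sample, at least 3.03-fold lower against 3 reads over the KO group. It fell when adjusted over the list alone (adjusted p = 0.014) and not over all genes. Haemoglobin genes share reads. Alas2, the erythroid enzyme of haem synthesis, was at 16.8 ± 1.25 and 10.4 ± 0.46 CPM. Hbb-bs was at 4.97 and 31.2 CPM in WT samples 1 and 2, and at 3.74 and 6.97 CPM in KO samples 1 and 2. The list was not called without WT sample 2 (median -0.17, adjusted p = 0.878), without KO sample 1 (median -0.69, adjusted p = 0.446), with a filter minimum of 5 CPM (median -0.94, adjusted p = 0.140), after quantile normalization (median -0.73, adjusted p = 0.089), or without the haemoglobin genes (median -0.65, adjusted p = 0.729).

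Germ cell lists were not called with all samples. Without KO sample 2, camera called meiosis higher (median 0.31, adjusted p = 0.0042) and elongating spermatids lower (median -0.08, adjusted p = 0.0076), along with ribosomal proteins (median -0.21, adjusted p = 0.0458) and blood cells. Without KO sample 1 the medians of meiosis, elongating spermatids and ribosomal proteins were -0.01, 0.03 and 0.15, each of the opposite sign, and none of these 3 lists was called (adjusted p = 0.806, 0.0571 and 0.0571). Of the 28 tested meiosis genes, 18 were higher in KO and 0 passed (camera adjusted p = 0.139). Hormad1 and Sycp1, components of meiotic chromosome axes and of the synaptonemal complex, were at 51.4 ± 6.21 and 55.4 ± 2.72 CPM in WT and at 75.7 ± 0.62 and 76.4 ± 2.08 CPM in KO; Mei1 was at 9.24 ± 1.80 and 15.7 ± 2.11 CPM. Among 18 spermatogonial genes, Sall4, a transcription factor of undifferentiated spermatogonia, had about 34 reads in WT and was below 0.5 reads in each KO sample, at least 4.29-fold lower against 3 reads over the KO group. Sall4 was the 1 member that fell when adjusted over the list alone (adjusted p = 0.0099), and over all genes it did not pass. Uchl1 was at 48.3 ± 2.03 and 65.2 ± 7.17 CPM and Dmrt1 at 20.1 ± 5.31 and 31.9 ± 7.39 CPM, and the list had a camera adjusted p of 0.806. In the 22 round spermatid genes, Spaca1 of the acrosome was at 134 ± 8.87 and 181 ± 2.34 CPM, Spaca4 at 86.9 ± 6.95 and 61.8 ± 2.43 CPM, and Izumo1, needed for sperm-egg fusion, at 94.9 ± 6.67 and 122 ± 14.2 CPM. The 23 genes of elongating spermatids included Tex37 at 183 ± 6.47 and 142 ± 14.1 CPM, the transition protein gene Tnp2 at 3823 ± 388 and 5107 ± 2070 CPM, and Hspa1l at 1230 ± 25.1 and 1110 ± 78.5 CPM. The 31 flagellum genes included Spef2 at 31.5 ± 6.35 and 20.2 ± 4.67 CPM, Tekt5 at 195 ± 14.3 and 162 ± 3.17 CPM, and Tekt2 at 415 ± 20.3 and 367 ± 34.0 CPM. In these 3 lists 0 members passed over all genes or over the list alone, and camera adjusted p was 0.899 in each.

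Of 17 tested Leydig cell genes 5 were higher, 12 were lower and 0 passed (camera adjusted p = 0.945). Insl3, a Leydig cell hormone, was at 1491 ± 37.5 CPM in WT and 1256 ± 31.4 CPM in KO, without overlap, a log2 fold change of -0.25 with SE 0.11 that did not pass. The steroidogenic genes Cyp17a1 and Star were at 88.0 ± 58.6 and 36.7 ± 18.5 CPM in WT and at 131 ± 5.67 and 57.1 ± 25.9 CPM in KO. Lhcgr, the luteinizing hormone receptor, was at 4.26 ± 2.10 and 7.53 ± 1.2 CPM. In the cholesterol synthesis list of 22 genes, Pmvk was at 17.2 ± 3.0 and 8.28 ± 1.5 CPM, Hmgcs1 at 34.3 ± 3.33 and 45.1 ± 9.05 CPM, and Srebf2 at 36.5 ± 0.32 and 27.3 ± 11.9 CPM, and the list did not pass (camera adjusted p = 0.899). In the Sertoli cell list of 22 genes (camera adjusted p = 0.945), Trf was at 26.7 ± 2.05 and 17.0 ± 9.91 CPM and Rhox5 at 8.53 ± 1.10 and 13.7 ± 5.18 CPM. Gdnf had about 9 reads in WT and 1 in KO, a depth-scaled ratio of 0.29 (exact 95% interval 0.0066 to 2.10).

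Other somatic cell lists had medians below 0 in some cases and above 0 in others, and 0 of their members passed over all genes or over their list alone. For 12 genes of peritubular myoid and vascular smooth muscle cells the median was -0.21 (camera adjusted p = 0.219), with Smtn at 10.9 ± 2.85 and 3.95 ± 0.00 CPM, Tagln at 13.8 ± 1.51 and 7.35 ± 0.94 CPM, and Myh11 at 24.1 ± 5.92 and 14.4 ± 2.85 CPM. Smtn had about 3.0 and 2.4 reads in the KO samples, so its KO SD of 0.00 does not show close agreement. For 12 genes of inflammatory cytokines and the interferon response the median was -0.55, or -0.45 with Usp18 at its bound (camera adjusted p = 0.219). Oasl2 had about 15 reads in WT and 1 in KO, a depth-scaled ratio of 0.17 (exact 95% interval 0.0041 to 1.13). Usp18 had about 8 reads in WT and none in KO. Its bound against 3 reads over the KO group was 0.99-fold, so no fall was established. Nfkb1 was at 19.4 ± 0.10 and 13.3 ± 2.47 CPM. For 22 extracellular matrix genes the median was -0.16 (camera adjusted p = 0.899), with Col6a1 at 16.0 ± 4.23 and 7.24 ± 5.51 CPM, Col4a2 at 22.9 ± 0.92 and 15.6 ± 3.21 CPM, and Lamc1 at 16.2 ± 2.24 and 9.85 ± 3.79 CPM. The 11 endothelial genes had a median of 0.22, with 7 higher and 4 lower (camera adjusted p = 0.899). Of these, the receptor gene Flt1 was at 13.3 ± 2.31 and 5.37 ± 1.87 CPM, Cldn5 at 9.87 ± 4.71 and 14.1 ± 2.75 CPM, and Cdh5 at 9.33 ± 1.42 and 6.82 ± 4.92 CPM. Among 14 macrophage genes (median 0.01, camera adjusted p = 0.899), C1qb was at 15.7 ± 0.79 and 10.4 ± 0.57 CPM, Adgre1 at 1.62 ± 0.31 and 3.43 ± 0.37 CPM, and Cx3cr1 at 2.64 ± 0.19 and 6.37 ± 5.19 CPM. Adgre1 had about 2.4 and 3.3 reads in the WT samples and 2.4 and 2.2 in the KO samples. Its levels thus rest on few reads in every sample, and its small SDs do not show close agreement. Lists of epididymis and tract epithelium (10 genes, median -0.22, camera adjusted p = 0.899) and of adipocytes (8 genes, median 0.0016, camera adjusted p = 0.945) included Epcam at 38.6 ± 1.99 and 31.1 ± 1.62 CPM and Lpl at 2.02 ± 0.44 and 3.06 ± 0.41 CPM. Of the adipocyte genes 4 were higher and 4 lower in KO. The KO mean of Lpl was below the value of 3 reads in each KO sample (4.01 and 5.02 CPM).

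Metabolic and signalling lists had 0 members past the test over all genes or over their list alone. In glycolysis and sperm energy metabolism (24 genes, camera adjusted p = 0.945), Gapdh was at 12.8 ± 3.71 and 7.39 ± 1.37 CPM and the glucose transporter gene Slc2a1 at 12.7 ± 0.03 and 7.88 ± 0.91 CPM. Eno1 was at 141 ± 23.2 and 215 ± 83.4 CPM, and summed with its near-copy Eno1b at 872 ± 34.1 and 671 ± 66.1 CPM. In oxidative phosphorylation (22 genes, camera adjusted p = 0.945), Uqcrc2 was at 72.0 ± 13.4 and 94.996 ± 15.4 CPM, the testis cytochrome gene Cyct at 39.1 ± 14.6 and 55.5 ± 6.69 CPM, and Ndufv1 at 104 ± 0.40 and 84.6 ± 17.9 CPM. In lipid metabolism (27 genes, camera adjusted p = 0.899), Fabp3 was at 85.7 ± 10.3 and 63.5 ± 17.8 CPM and Scd2 at 96.1 ± 3.26 and 80.2 ± 14.2 CPM. Ppara had about 20 reads in WT and 3 in KO, a depth-scaled ratio of 0.39 (exact 95% interval 0.075 to 1.32). In insulin and IGF signalling (22 genes, camera adjusted p = 0.899), Mtor, a kinase gene on chromosome 4, was at 277 ± 8.52 and 213 ± 31.0 CPM and the insulin receptor gene Insr at 12.9 ± 4.38 and 23.2 ± 2.59 CPM. In cAMP and G protein signalling (31 genes, camera adjusted p = 0.899), Rapgef3 was at 16.2 ± 0.97 and 8.89 ± 0.75 CPM, Adcy9 at 9.04 ± 0.17 and 16.9 ± 4.86 CPM, and Pde8b at 9.28 ± 2.47 and 4.00 ± 1.41 CPM.

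In the stress, growth and clock lists, 0 members passed over all genes or over their list alone. The 17 immediate early genes had a median of -0.21, or -0.14 with Ier3 at its bound (camera adjusted p = 0.219). Egr1 had about 29 reads in WT and 2 in KO, a ratio of 0.181 (exact 95% interval 0.021 to 0.714). Ier3 had about 8 reads in WT and none in KO, at least 1.02-fold lower against 3 reads over the KO group, which is hardly any fall. Jun was at 16.1 ± 3.86 and 7.72 ± 1.94 CPM. Among 20 apoptosis genes (camera adjusted p = 0.489), Bid was at 3.39 ± 0.02 and 10.01 ± 2.64 CPM, Bcl2l1 at 84.6 ± 1.22 and 105 ± 10.3 CPM, and Apaf1 at 7.30 ± 2.19 and 12.9 ± 4.03 CPM. Among 24 oxidative stress genes (camera adjusted p = 0.899), Gstm1 was at 413 ± 16.3 and 318 ± 64.6 CPM, Prdx1 at 53.1 ± 3.09 and 69.8 ± 0.57 CPM, and Txnrd1 at 28.7 ± 0.55 and 21.6 ± 4.73 CPM. Among 21 genes of heat shock and the unfolded protein response (camera adjusted p = 0.806), Dnajb1 was at 466 ± 18.1 and 388 ± 21.6 CPM, Pdia3 at 287 ± 31.1 and 343 ± 23.8 CPM, and Hspe1 at 8.80 ± 0.71 and 15.2 ± 4.51 CPM. Among 24 cytosolic ribosomal protein genes, which share reads with pseudogenes, Rpl37 was at 75.8 ± 4.63 and 46.2 ± 12.5 CPM, Rps14 at 304 ± 33.6 and 455 ± 143 CPM, and Rpl10 at 23.8 ± 4.36 and 35.4 ± 6.66 CPM (camera adjusted p = 0.945). Among 18 circadian clock genes (camera adjusted p = 0.945), Rora, a nuclear receptor of the clock, was at 37.3 ± 0.89 and 18.7 ± 0.01 CPM (adjusted p over the list alone 0.074), Arntl at 5.64 ± 0.42 and 9.59 ± 2.54 CPM, and Ciart at 5.90 ± 2.87 and 3.68 ± 0.47 CPM.

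**Figure D3:**
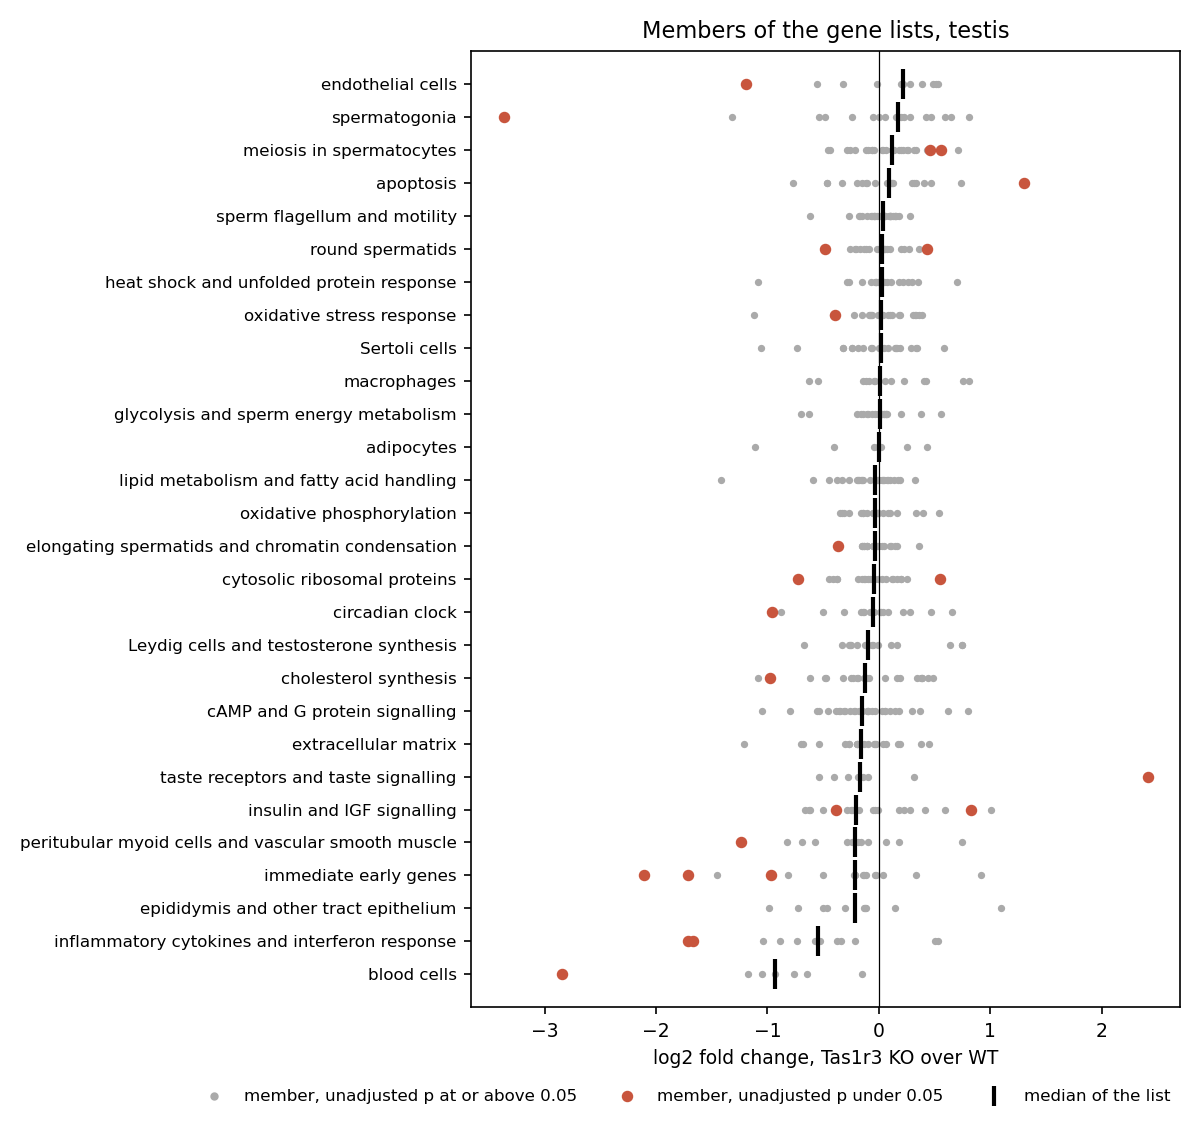
Log2 fold change of KO over WT (horizontal axis) of the tested members of 28 gene lists (vertical axis); red points are members with an unadjusted limma p under 0.05, grey points are other members and black ticks are list medians. The median of the blood cell list is farthest from 0, at -0.94.

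In 8 lists the median, the mean and the camera test did not share a sign: taste signalling, Sertoli cells, spermatogonia, adipocytes, glycolysis, oxidative phosphorylation, oxidative stress and ribosomal proteins. With fry, 0 lists moved on balance in one direction. Its mixed test, which asks for change in either direction, gave an adjusted p of 0.0498 for taste signalling and for spermatogonia, the lists that hold Tas1r1 and Sall4.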

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

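Precision weights, the window without close neighbours, the 10 Mb window and the blood cell list without haemoglobin genes were chosen after seeing the data; the other alternatives were planned. The number of genes higher in KO, 0 with all samples, was 4 with precision weights and 1 to 434 with 1 sample left out. The number lower, 1 with all samples, was 0 without a mean trend, 0 with a pseudocount of 0.1 and 3 to 1029 with 1 sample left out. When a KO sample is left out the lone KO sample is assumed to vary like the WT pair, which is deeper. The number of lists called, 1 with all samples, was 0 with an estimated correlation, 0 with a filter minimum of 5 CPM, 0 after quantile normalization, 0 without haemoglobin genes and 0 to 4 with 1 sample left out. The Tas1r3 log2 fold change, -3.54 with all samples, was -5.48 with a pseudocount of 0.1 and -1.96 with a pseudocount of 5, and ranged from -4.16 to -2.93 with 1 sample left out. It passed without KO sample 1 (adjusted p = 1.61e-12) and without KO sample 2 (adjusted p = 2.51e-07), and not without either WT sample. The share of window genes with p under 0.05 was 8.70% without a mean trend, against 6.30% on other chromosomes, and 5.56% to 31.9% with 1 sample left out. The lowest of these, without WT sample 1, stood against 1.15% elsewhere and the highest, without KO sample 1, against 23.6%; the shares were 8.79% against 1.15% without WT sample 2 and 28.9% against 18.0% without KO sample 2. The causes of the changes under other settings were not tested.

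With the replicate number as a replicate block, 6 genes were higher and 17 lower, and the Tas1r3 log2 fold change of -3.54 passed (adjusted p = 3.02e-04). Samples with the same number did not deviate together (r = -0.01 over all tested genes, which are not independent), so the numbers are not taken to pair the samples.

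After quantile normalization Retn reversed to 0.39. Rn18s went to 0.00 without changing sign, an outcome fixed in advance, since this gives the highest gene of each library 1 common value. With 1 sample left out the log2 fold change crossed 0 for Cdh5 (-1.24 to 0.14), Gnat1 (-1.61 to 0.53), Hbb-bs (-2.39 to 0.042), Itpr3 (-0.43 to 0.048), Retn (-1.11 to 0.31), Rnase10 (-0.025 to 2.22), Ros1 (-2.28 to 0.31), Tas1r2 (-0.71 to 0.17) and Tnp2 (-0.066 to 0.78). For named genes and single lists, apart from samples left out, 907 of 924 comparisons kept direction and side of the threshold, 5 lost the call, 10 gained it and 2 reversed or went to 0 (Retn and Rn18s). Much of this agreement was fixed in advance. The filter, mean trend and block settings leave the log2 fold change of a gene unchanged. Apart from Ptchd3 and the blood cell list, none of these results was called with all samples. Count models on recovered reads were planned and not run, because only 23.0% to 48.1% of genes came out whole. KO depth limits low genes: 3 reads are 4.01 and 5.02 CPM in the KO samples, against 1.74 and 1.66 CPM in WT.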

Other observations

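All tests of explanations in this part were chosen after the results they bear on had been seen. Tests over windows count neighbouring genes of the same samples as independent, which they need not be.

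Small p-values on chromosome 4 were also frequent beyond the window fixed in advance. Among 537 windows of 5 Mb across the genome, the one from 145 to 150 Mb of chromosome 4 had 11 of 57 genes with an unadjusted p under 0.05 (exact binomial test, adjusted p = 0.0325). The next by p was its neighbour from 150 to 155 Mb, with 9 of 52 genes (exact binomial test, adjusted p = 0.174). The window from 155 to 160 Mb, which holds Tas1r3 itself, had 5 of 49 genes, Tas1r3 included. It ranked 31 of 537 (exact binomial test, unadjusted p = 0.079). The windows across the genome were not examined in the splits that mixed the genotypes. Within 2 Mb of Tas1r3 the share was 10.3% of 68 genes (odds ratio 2.39, 95% interval 0.92 to 5.25, Fisher's exact p = 0.036), and within 20 Mb it was 12.4% of 266 genes, 17 higher and 16 lower. Beyond 20 Mb it was 4.37% of 847 genes of the chromosome. With 4 samples there are only 3 splits, too few for a share under 0.05; the real split gave an odds ratio of 3.12 in the 5 Mb window, and the highest of the other splits gave 2.19. That split, WT sample 1 and KO sample 2 against WT sample 2 and KO sample 1, had 9.78% of window genes at p under 0.05 against 4.71% elsewhere (Fisher's exact p = 0.0416). Over all genes the other splits gave 841 and 679 genes at an unadjusted limma p under 0.05, against 833 for the real split, and each of the 3 splits gave 1 gene past the adjusted threshold.

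Several explanations were weighed for the small p-values around Tas1r3. A split that mixed the genotypes also reached a Fisher's exact p of 0.0416 in the window, so the p-values below are approximate. The depth difference acts through a gene's level, and random gene sets matched on mean level reached the count of 12 in a fraction of 9.0e-04 of 10000 draws, which argues against depth as the whole cause. Without the genes within 1 Mb of Tas1r3, 7 of 41 genes remained (Fisher's exact p = 0.0025). Small p-values were thus not confined to immediate neighbours of the targeted allele, which argues against an effect on these alone if genes vary independently. Loss of reads that carry a strain variant would lower KO values, yet genes higher in KO were in excess (Fisher's exact p = 2.29e-04). That argues against such loss as the only cause. Genes lower in KO at an unadjusted p under 0.05 were 5.43% of the window and 3.28% of other chromosomes (Fisher's exact p = 0.232). Loss of reads at some of these lower genes stays open. A linked chromosome segment from another strain may contribute, as the rest of the chromosome beyond 20 Mb was at the share of other chromosomes (Fisher's exact p = 0.866); this, and a response of these genes to loss of TAS1R3, remain open, because no strain variants were measured here and a segment linked to the targeted allele would be present in the same samples that lack TAS1R3.

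Part of the excess of lower genes among small p-values may come from depth. Unchanged genes simulated at these depths gave a median of 61.9% lower over 100 draws (57.1% to 66.8%). The 70.8% in the data was above every draw. The simulated genes all had the spread of genes at 500 CPM or more, so the simulation cannot tell whether depth gives the remainder. The weighted fit gave 42.4%, but its pseudocount in reads adds more CPM in the KO samples than in WT. Rescaling by the trimmed mean of M values left 68.9% lower. It moved the median log2 fold change only from -0.05 to -0.04, so whether a scaling factor per library adds to the excess stays open. Quantile normalization brought the median to -0.0035 and gave 54.1%. It makes the distributions of all libraries equal, so that share does not test depth. A broad reduction of expression in KO testis was not tested separately from depth, as each genotype has its own depth.

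The opposite differences of Smok3b and Smok3c may come from reads divided between near-identical copies. The level summed over 3 copies differed by 0.15 on the log2 scale, less than its pooled SD of 0.67, while single copies ran from -3.49 to 3.87. With n = 2 and a KO level of 33.0 ± 20.2 CPM, that spread could hide a sizeable difference, so the sum cannot decide. A sequence difference between the genotypes at these copies stays open and was not tested.

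In other near-copy families, the summed level of 4 Dynlt1 genes was 1029 ± 430 CPM in WT and 2136 ± 1202 CPM in KO, and that of 2 Rsph3 genes 646 ± 84.7 and 488 ± 85.9 CPM.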
